A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

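Small RNA was sequenced from fission yeast (Schizosaccharomyces pombe) in 6 libraries, 1 per sample of the series, and all 6 sample columns were used. Per the labels, cells grew in rich YES medium to an optical density of 0.5, total RNA was extracted with hot phenol, the RNA of 18 to 28 nt was purified on a gel, and libraries were made with the Illumina TruSeq small RNA protocol. Per the submitters' processing notes, CASAVA 1.8, Bowtie 0.9.9.1 and MACS (no version given) were used; the role of each and the genome build are not given in the sources used here.

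The deposited file holds 1 list of 11033 MACS peaks shared by all libraries and, for each peak and library, a value in a unit named here signal. The deposited signal was worked out from the values themselves as the reads on the peak multiplied by the mean peak width, 71.0 bp, and divided by the width of the peak. The columns of spb80 and of the library labelled dcr delta carry an added 8, which was subtracted. The dcr delta column steps by 1.48 per read. With these terms removed, 73.8 to 92.4% of the values of a library fell within 0.01 of a whole read, and 95.9 to 97.5% on a whole, 1/2 or 1/3 read, so reads with several matches in the genome appear to be shared out in fractions. Identical repeat copies therefore hold identical values and are not independent. The list names no strand and no caller score.

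Peaks were placed on the RefSeq annotation of the current S. pombe assembly, ASM294v3. At unshifted positions 212 of 243 tRNA, snoRNA and snRNA genes held a peak, against 38 to 60 when peaks were moved by 200, 500 or 2000 bp in either direction, and the unshifted position was best in 14 of 14 bins of 1 Mb. A peak was given to a feature on an overlap of at least 1 bp. Coordinates refer to this assembly.

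Signal was scaled between libraries with trimmed-mean (TMM) factors computed over the 6 libraries, trimming 30% of log ratios and 5% of mean levels, and the 25% of peaks with the lowest mean were dropped in each comparison. Levels are given as normalised reads per peak of mean width, as mean ± SD over the libraries of an arm. The test was limma 3.58.1 in R 4.3.3 on log2 of normalised signal plus 1, with a trend in the prior variance, 2-sided, and Benjamini-Hochberg adjustment over all tested peaks at 0.05. The fixed choices of groups, comparisons, test for this kind of value, filter, pseudocount, gene lists and most alternatives were made before the data were examined; the removal of the added 8 followed from the values. The counting test first in line for a file of read counts was not run, because the file holds signal and not counts.

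The library labelled dcr delta was compared with 3 wild-type libraries at 30 °C, 1 of strain spb80 and 2 of strain spb75. The spb75 libraries after 8 hours and after 7 days at 37 °C were each compared with the 2 spb75 libraries at 30 °C. Each test has 1 library on 1 side, which was assumed to vary like the others. The labels do not say whether libraries come from separate cultures, so p-values measure at most the spread between samples. The dcr delta test has 2 residual and 6.83 prior degrees of freedom, and the heat tests 1 and 15.5. The variance used for a peak is thus mostly borrowed from other peaks of similar level. The libraries after 8 hours and 7 days at 37 °C were set against each other, and spb80 against spb75, as values without a test, a choice fixed beforehand; a limma test of the same form as the others could have been run and was not. Log2 levels of all pairs of libraries were correlated across peaks without p-values, because peaks are not replicates.

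Fixed lists covered pericentromeric repeats, the silent mating-type region (2.11 to 2.14 Mb of chromosome II), subtelomeres (the outer 50 kb of chromosomes I and II), rRNA, tRNA, snRNA and snoRNA, other non-coding RNA, the mitochondrial genome, Tf2 retrotransposons and LTRs, heat shock and chaperone genes, stress genes, RNAi and heterochromatin genes, meiotic genes, housekeeping genes and ribosomal protein genes. Of these, 18 of 19 heat shock, 15 of 16 stress, 12 of 19 RNAi and heterochromatin, 6 of 12 meiotic and 11 of 11 housekeeping genes held a peak. The median of each list was ranked among the medians of 10000 random sets of peaks of equal size matched on level in 20 bins. Named peaks are, per comparison, the 10 largest rises and the 10 largest falls (past the threshold where at least 10 passed), with neighbours in 1 feature or within 1 kb merged, and the 3 peaks with the highest mean in each list. Other peaks are named where a count is small or a list call is described, and these were chosen after their values were seen.

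Shares of reads in a single library carry Wilson intervals at 95%, and ratios with 1 to 3 reads on the lower side carry Clopper-Pearson intervals at 95%. A ratio against 0 reads is a bound computed from 3 reads over that arm. These are PCR reads without molecular identifiers, so intervals and bounds cover counting error only. The tests were tried on simulated data with 200 changed peaks, rises and falls counted together. The dcr delta test recovered 32.8% of changes of 4-fold, 98.0% of 16-fold and 100% of 64-fold, with 8, 21 and 25 false calls. The test at 8 hours recovered 29.8%, 97.3% and 100%, with 23, 28 and 7 false calls. At 4-fold and 16-fold both tests made more false calls than the adjusted p threshold allows, as did dcr delta at 64-fold. The simulation took 1 dispersion, 0.115, for both tests. Recovery and false calls hold for that spread only and may differ for real peaks and across the wild-type strains.

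The alternatives were median-of-ratios factors, total reads over peaks, TMM factors without rRNA, tRNA, snRNA and snoRNA peaks, no filter, pseudocounts of 0.1 and 10, 1 fit over all 6 libraries, other choices of control libraries (with spb80 as the only control, the spb75 libraries give the spread), both 37 °C libraries as 1 group, each control library left out, and a stricter overlap. Alternatives added after the values were seen were limma with voom weights on reads, reads summed per gene, the added 8 kept, and pericentromeric peaks without tRNA genes. Lists, ratios and plots were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.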

Results

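Small RNAs were profiled in 6 libraries of fission yeast. At 30 °C there was 1 library of wild-type strain spb80, 1 of strain spb309, labelled dcr delta (dcr1 encodes Dicer, the enzyme that cuts double-stranded RNA into siRNA), and 2 of wild-type strain spb75. Strain spb75 was also sampled after 8 hours and after 7 days at 37 °C, with 1 library each. The series title names Dicer and Hsp104, a chaperone that dissolves protein aggregates. Reads over the peaks came to 11037742 for spb80, 7106616 for dcr delta, 15723318 and 5790804 for spb75 replicates 1 and 2, 12910992 at 8 hours and 7025811 at 7 days. The median peak held 19 to 47 reads. Arms of 1 library have no replicate error.

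The 11033 peaks lay on chromosomes I (4990), II (3991) and III (2052) and had a median width of 51 bp. Most, 9526 peaks or 86.3%, fell on protein-coding genes, 3239 of them in all, with 6089 peaks in coding sequence, 3394 in UTRs and 43 in introns. A further 703 peaks fell on lncRNA genes, 159 on tRNA, 63 on snoRNA, 45 on rRNA and 6 on snRNA genes, and 513 on no annotated feature. All peaks lay on these chromosomes, so the planned mitochondrial list stayed empty. Whether the mitochondrial genome was part of the mapping reference is not given, so this says nothing about mitochondrial small RNA. By reads the order was different. In wild type at 30 °C, tRNA genes took 34.9% ± 3.76 (SD, n = 3) of reads over peaks, rRNA genes 27.9% ± 4.40, pericentromeric repeats without a tRNA gene 18.8% ± 3.33 and protein-coding genes 15.8% ± 4.75.

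**Figure D1:**
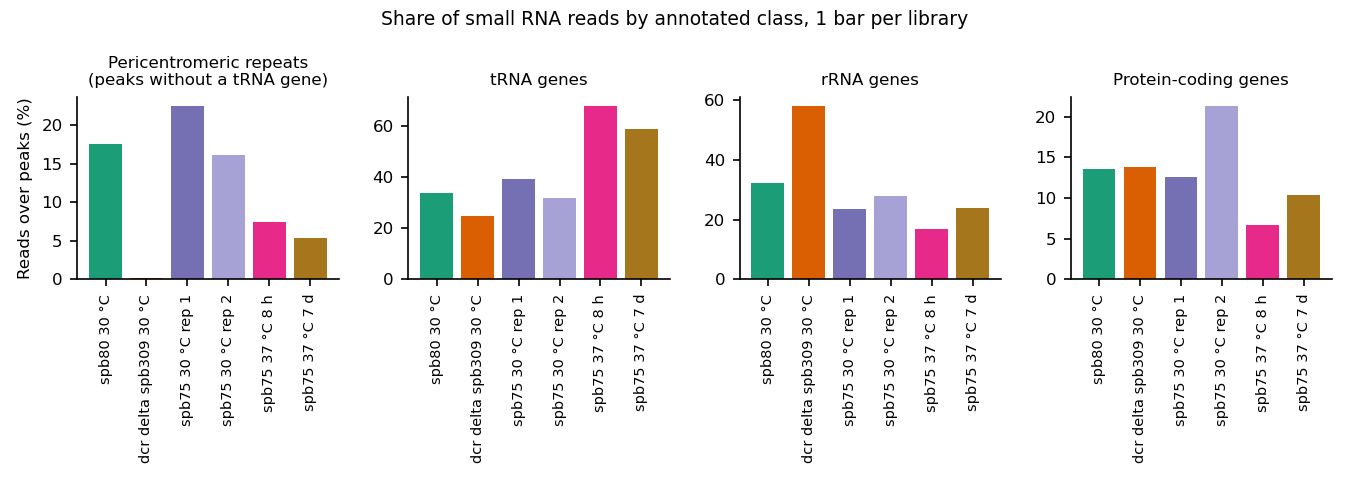
Bars give the percent of each library's reads over peaks that fell on pericentromeric repeats (peaks without a tRNA gene), tRNA genes, rRNA genes and protein-coding genes, 1 bar per library, each panel with its own axis from 0. The pericentromeric share was 0.116% in the library labelled dcr delta, 7.46% after 8 hours and 5.41% after 7 days at 37 °C, against 16.2 to 22.5% in the 3 wild-type libraries at 30 °C.

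The correlation of libraries across the 8274 peaks with higher signal, a comparison the series title points to, was highest by Pearson's r among wild-type libraries at 30 °C. Across peaks, which are not independent replicates, spb80 and spb75 replicate 2 had Pearson's r = 0.893 and Spearman's rho = 0.812, and the spb75 replicates r = 0.892 and rho = 0.813. The lowest of the 15 pairs was dcr delta with the 8 hour library (r = 0.760, rho = 0.604). By rho, dcr delta with spb80 (0.812) was level with these and above spb80 with spb75 replicate 1 (0.768). The dcr delta library reached r = 0.850 with spb80 and 0.842 with the 7 day library, and the 2 libraries at 37 °C reached 0.855 with each other.

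Which small RNAs need Dicer was asked by comparing the library labelled dcr delta with wild type at 30 °C. Small RNAs from the centromere repeats and chromosome ends were all but lost. Pericentromeric repeats, the dg and dh copies that flank each centromere and are packed into heterochromatin, fell from 18.8% ± 3.33 (SD, n = 3) of reads to 0.116% (95% Wilson interval 0.114 to 0.119%). Subtelomeres fell from 0.190% ± 0.0365 to 0.00920% (0.00852 to 0.00994%). Outside these lists a lncRNA at a centromere border, a matching copy of a pericentromeric peak, and a peak in tho3 also fell. Peaks in eno102 and snoR58 rose.

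By limma, 72 of 8274 peaks fell and 2 rose, with 515 at an unadjusted p under 0.05. The 72 comprised 39 of 41 pericentromeric peaks, 31 of 47 subtelomeric peaks, the lncRNA IRC1-L at the left border of centromere I and the tho3 peak. IRC1-L matches the pericentromeric copy SPNCRNA.3688 and is no separate finding. They held 52 distinct read profiles, with fitted log2 ratios from -8.37 to -4.83 and a median of -6.92. Without the spb80 library or without spb75 replicate 2 the rising count was 7 in each case, and it was 8 when libraries were scaled by total reads.

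In the centromeres, the lncRNA SPNCRNA.3679 (I, 3761774 to 3764218) went from 2853 ± 1374 normalised reads (n = 3) to 11, a log2 ratio of -7.78 (SE 0.59, adjusted p = 0.000161). SPNCRNA.3673 (I, 3753991 to 3755825) went from 2743 ± 1087 to 15.5, a ratio of -7.29. The largest fall was that of the matching copies IRC1-L (I, 3752846 to 3753828) and SPNCRNA.3688 (I, 3789279 to 3790261), each at -8.37 (SE 0.83, adjusted p = 0.000529). On chromosome III the copies SPNCRNA.7213, SPNCRNA.7218, SPNCRNA.7223 and SPNCRNA.7226 held identical values and fell by 8.28 (SE 0.69). SPNCRNA.372 on chromosome II (1638090 to 1638430) fell by 8.27 (SE 0.70), and the copies SPNCRNA.7199, SPNCRNA.7192 and SPNCRNA.5256 fell by 8.26 (SE 0.71). The pericentromeric list had a median log2 ratio of -7.13 over 41 peaks, or -7.08 over 28 distinct profiles, below every one of the 10000 matched random sets. Its 2 peaks that did not pass overlap tRNA genes, and that at SPATRNAGLU.04 (I, 3776742 to 3776862) had a ratio of -0.83 (SE 0.84, adjusted p = 0.918). The count was again 39 when adjusted over the list alone.

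**Figure D2:**
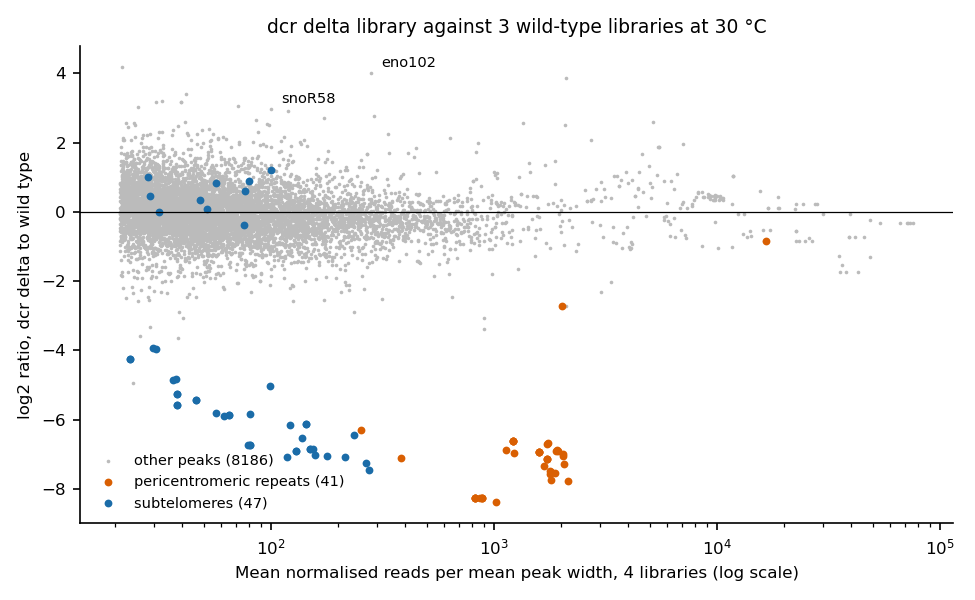
Each point is 1 of 8274 tested peaks, with the mean normalised reads of the 4 libraries on a log axis and the log2 ratio of the dcr delta library to the 3 wild-type libraries at 30 °C on the other. Pericentromeric peaks (orange) centre on -7.13 and subtelomeric peaks (blue) on -5.82, with eno102 and snoR58 the 2 peaks that rose.

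**Figure D3:**
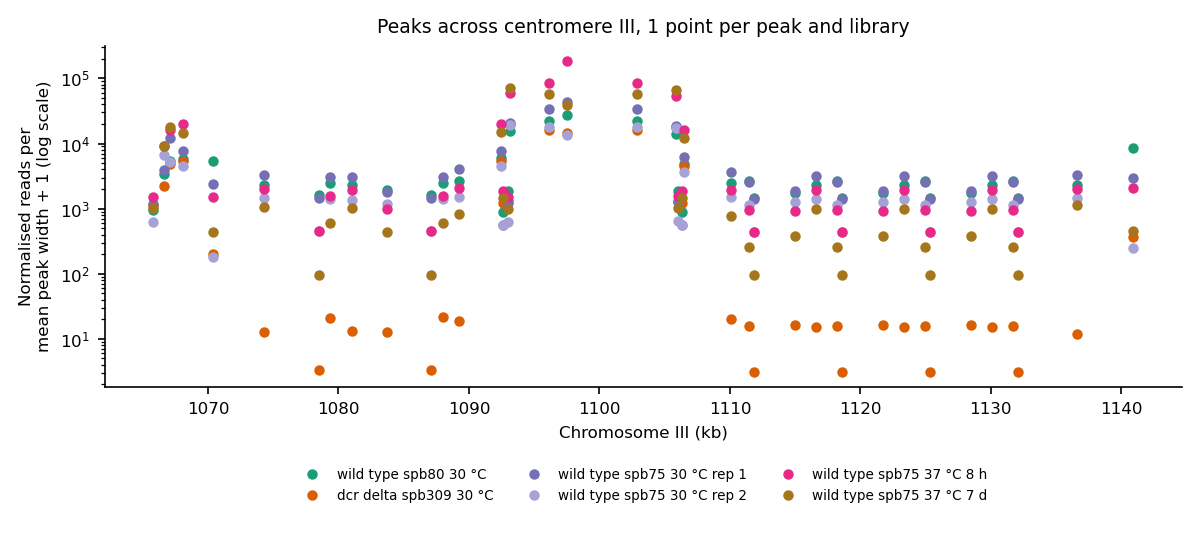
Points give the normalised reads per mean peak width plus 1, on a log axis, of each peak across centromere III in each of the 6 libraries, against position in kb on chromosome III. Over SPNCRNA.7189 (1073013 to 1075517) the dcr delta library held 11.6 against 1462 to 3308 in wild type at 30 °C, while tRNA peaks of the central part held similar levels in both.

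At the chromosome ends, tlh1, a telomere-linked helicase gene (I, 3120 to 3685, coding sequence), went from 355 ± 109 normalised reads (n = 3) to 1.28, a log2 ratio of -7.24 (SE 0.50, adjusted p = 0.000161). Its counterpart tlh2 on chromosome II had log2 ratios of -7.07 (4528382 to 4529455, SE 0.50) and -7.06 (4528099 to 4528380, SE 0.66, 470-fold with an interval of 130 to 3886). The subtelomeric lncRNA SPNCRNA.4508 (I, 5573573 to 5573690) went from 365 ± 100 to 1.02, a ratio of 285-fold with an interval of 78.7 to 2352, and SPNCRNA.2012 (I, 17694 to 17850) fell by 6.45 (SE 0.48). The list had a median of -5.82 over 47 peaks, or -4.40 with the 22 members at 0 reads in dcr delta set at their bounds. When adjusted over the list alone, 35 subtelomeric peaks fell. The peak away from both regions and the centromere border was in tho3, a subunit of the mRNA export complex THO (III, 738054 to 738081, coding sequence), with 8, 27 and 15 reads in wild type and 0 in dcr delta, at least 3.86-fold lower (adjusted p = 0.0412), a call lost with pseudocount 10, with voom weights, with the added 8 kept and with spb80 as the only control. With replicate 1 or replicate 2 left out, the tho3 peak fell below the filter and was not tested.

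The 2 peaks that rose were in eno102, an enolase gene (II, 58992 to 59029, coding sequence), and in the snoRNA gene snoR58 (I, 5366230 to 5366281). The eno102 peak went from 57.8 ± 5.91 normalised reads (n = 3) to 950, a log2 ratio of 4.02 (SE 0.44, adjusted p = 0.00121), and snoR58 rose by 2.96 (SE 0.54, adjusted p = 0.0454). The snoR58 call was lost with median-of-ratios factors, without the filter, without spb75 replicate 2 and with spb80 as the only control. Larger ratios that missed the threshold were 4.18 (SE 1.22) in cta3, a calcium pump gene, where wild-type libraries held 1 to 9 reads, and 3.86 (SE 1.07) at a peak on no feature (III, 814777 to 814936). There spb80 held 4606 reads, the spb75 replicates 599 and 664, and dcr delta 12643.5. The 10 largest ratios also included, short of the threshold, SPBC32F12.07C (3.41), snR92 (3.18), SPNCRNA.1082 (3.18), ecl1 (3.17), obr1 (3.06) and caf5 (3.03). In dcr1 itself, a UTR peak (III, 1505607 to 1505661) had a ratio of 3.21 (SE 0.71, adjusted p = 0.143), or adjusted p = 0.0252 adjusted over the list alone, with 69 reads in dcr delta against 5 to 16 in wild type. All 5 dcr1 peaks held more reads in dcr delta than in any wild-type library at 30 °C, among them 3 in coding sequence with 21 against 0 to 2, 20 against 0 to 6 and 115 against 42 to 60 reads. The labels do not say which part of dcr1 was deleted. With reads summed per gene, dcr1 rose by 2.28 (SE 0.39, adjusted p = 0.0430), ecl1 by 2.81 (SE 0.48) and eno102 by 3.31 (SE 0.43).

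Genes for snRNA and snoRNA lay above wild type as a group. Their share of reads was 0.788% in dcr delta against 0.294% ± 0.0491 (n = 3), and 53 of 61 peaks lay above 0 with a median of 1.02. Relative to the wild-type mean, the median log2 level of these genes was 0.49 in spb80 and -0.15 and -0.26 in spb75 replicates 1 and 2. The wild-type strain spb80 thus also lay above spb75. Adjusted over the list alone 7 rose, among them the spliceosomal RNAs snu1 (2.57, SE 0.52) and snu2 (2.51, SE 0.53), and also snu32 (1.99, SE 0.55). Of the list 1 peak, snoR58, passed over all peaks. The share of rRNA was 58.0% against 27.9% ± 4.40, yet the median of its 45 peaks was 0.45, turned to -0.06 without spb75 replicate 2, and no peak passed limma, with 5 at an unadjusted p under 0.05. The 87 heat shock and chaperone peaks had a median of 0.48 with 62 above 0, above all random sets, but 0 passed, also adjusted over the list alone, with 8 at an unadjusted p under 0.05. The housekeeping list, with a median of 0.12, also lay above all random sets, as did rRNA, snRNA and snoRNA, and other non-coding RNA. The rank therefore does not single out heat shock genes. For hsp16, a small heat shock protein gene, dcr delta held 2805 normalised reads summed over its peaks against 338, 353 and 1300 in wild type.

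Medians of the other lists in dcr delta were 0.09 for 159 tRNA peaks (-0.10 without spb75 replicate 2), -0.04 for stress genes (0.09 without spb75 replicate 2), 0.18 for RNAi and heterochromatin genes (0.06 without replicate 2), -0.21 for meiotic genes (0.20 without spb80), 0.12 for housekeeping genes (-0.06 without replicate 1), -0.25 for ribosomal protein genes and 0.27 for other non-coding RNA (0.12 without replicate 2), and -1.0 for the 1 Tf2 or LTR peak tested. Of the RNAi and heterochromatin peaks 0 passed limma over all peaks, with 3 at an unadjusted p under 0.05. In the mating-type region (median -0.54, 21 peaks) 0 passed limma over all peaks, with 8 at an unadjusted p under 0.05, and adjusted over the list alone 5 peaks of rpt6, a proteasome subunit gene, fell and snR92 rose. The list takes every peak in its window, rpt6 and snR92 included. How many of its peaks lie in silenced sequence was not examined. Of other non-coding RNA 25 peaks fell over all peaks, every one a subtelomeric peak counted above, and adjusted over the list alone 28 fell, all subtelomeric but SPNCRNA.1223, and 3 rose. For tRNA, rRNA, stress, meiotic, housekeeping and ribosomal protein genes and Tf2 or LTR, 0 passed in either form by limma, with 1, 5, 8, 1, 0, 7 and 0 peaks at an unadjusted p under 0.05. With reads summed per gene, however, the stress gene cta3 rose by 3.43 (SE 0.65) when adjusted over the list alone.

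How small RNAs changed on a shift to heat was asked by comparing spb75 after 8 hours at 37 °C with the same strain at 30 °C. Fragments of tRNA genes took 67.7% of reads (95% Wilson interval 67.6 to 67.7%) against 35.5% ± 5.07 (SD, n = 2), and pericentromeric repeats 7.46% (7.44 to 7.47%) against 19.3% ± 4.49. Among single peaks, those that rose included eno102, fes1, a nucleotide exchange factor of the chaperone Hsp70, zym1, a metallothionein gene, swi6, the gene of the heterochromatin protein HP1, and hsp104. The biotin transporter gene vht1 fell.

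By limma 83 peaks rose, 75 of them in 64 protein-coding genes, and 19 fell, 15 of them in 12 coding genes, with 1303 of 8274 at an unadjusted p under 0.05. Rises ran from 2.29 to 5.32 on the log2 scale with a median of 2.75 and falls from -5.55 to -2.29. The calls depend on the settings of the fit. Total-read scaling left 0 rising and 1 falling, no filter left 4 and 1, and all 3 wild-type libraries as control left 1 and 1. Reads summed per gene left 2 rising (eno102 and SPBC24C6.03) and 0 falling. The prior degrees of freedom also differed, 15.5 here, 10.3 without the filter, 6.67 with 3 wild-type libraries and infinite with total reads. Which of these moved the counts was not tested. In simulated data with 200 peaks changed 4-fold, this test recovered 29.8% of the rises and falls together and made 23 false calls, more than a threshold of 0.05 allows. Total-read scaling moved the median of all peaks to -1.11, so changes are given relative to the other peaks.

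The largest rise was at a peak on no feature (II, 1947899 to 1947951), from 55.2 ± 42.6 normalised reads (n = 2) to 1894, a log2 ratio of 5.32 (SE 0.67, adjusted p = 0.00138). The eno102 peak went from 58.9 ± 7.92 to 1679 (4.82, SE 0.56, adjusted p = 0.000719). In fes1 (II, 3991324 to 3991381, coding sequence) the level went from 17.2 ± 14.9 to 327 (4.47, SE 0.84, adjusted p = 0.0242), and a neighbouring peak rose by 3.71 (SE 0.55). SPBC24C6.03, a prolyl-tRNA ligase gene, rose by 4.04 in its UTR (II, 2322871 to 2322961, SE 0.53), and zym1 by 3.90 (I, 2381664 to 2381707, SE 0.60, adjusted p = 0.00767). In swi6 (I, 1703908 to 1703946, coding sequence) the level went from 30.5 ± 2.54 to 428 (3.77, SE 0.53, adjusted p = 0.00376). The other largest rises were in erg8, a mevalonate pathway kinase gene (3.80, SE 0.78), isp6, a vacuolar protease gene (3.73, SE 0.80), SPCPB16A4.06C (3.69, SE 0.87) and SPBC11C11.01 (3.50, SE 0.60).

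Of the 19 falls, vht1 had the largest (I, 4959647 to 4959676, coding sequence), with 82 and 119 reads at 30 °C and 1 at 8 hours, 61.7-fold lower with an interval of 10.9 to 2448, and 4 vht1 peaks fell. A related transporter gene, SPAC1B3.15C (I, 4957714 to 4957764), held 3 reads, 18.1-fold lower (6.10 to 88.6). A peak on no feature (II, 73669 to 73713) held 1 read, 22.7-fold lower (3.95 to 909). The gene of the ribosome assembly factor midasin, mdn1, held 2.5 reads, rounded to 3 for its ratio, 7.67-fold lower (2.53 to 38.0). The others of the 10 largest falls were SPNCRNA.2089 (-3.22), SPNCRNA.5053 (-3.19), meu10 (-2.84), SPBC1271.10C (-2.77), SPAC29E6.06C (-2.72) and cox24 (-2.63).

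Heat shock and chaperone peaks at 8 hours had a median of 0.42 with 60 of 87 above 0, or -0.69 under total-read scaling, where the median of all peaks was -1.11, and 0.77 without spb75 replicate 2. Of these peaks 1 rose, in hsp104 (II, 3614330 to 3614386, coding sequence), from 46.9 ± 25.7 (n = 2) to 262 normalised reads (2.57, SE 0.59, adjusted p = 0.0439). Adjusted over the list alone 7 rose, in hsp104 (2.57 and 2.99), hsp16 (2.46 and 2.45), ssa1 (2.85), wos2 (2.23) and hsp9 (2.19), genes of chaperones and small heat shock proteins. With reads summed per gene, limma called 0 of the 20 genes under these peaks, overlapping neighbours such as nse1 included, in either form, with 6 at an unadjusted p under 0.05. Among stress genes, with a median of 0.66 or -0.53 under total-read scaling, 3 peaks rose, all in zym1. Adjusted over the list alone 10 rose, 6 in zym1, 2 in gpd1 and 1 each in gst2 and gpx1, but with reads summed per gene 1 of 12 genes did, and gst2 stood at -0.47. Of the RNAi and heterochromatin peaks 2 rose, in swi6 and in eri1, a nuclease of siRNA (II, 1321048 to 1321084, 2.74, SE 0.57, adjusted p = 0.0342), and adjusted over the list alone 3, with a dcr1 peak added (2.16). With reads summed per gene swi6 stood at 2.21 (SE 0.46) and eri1 at 0.92 (SE 0.50), and neither was called over all genes. That list had a median of 0.65, or -0.38 under total-read scaling.

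**Figure D4:**
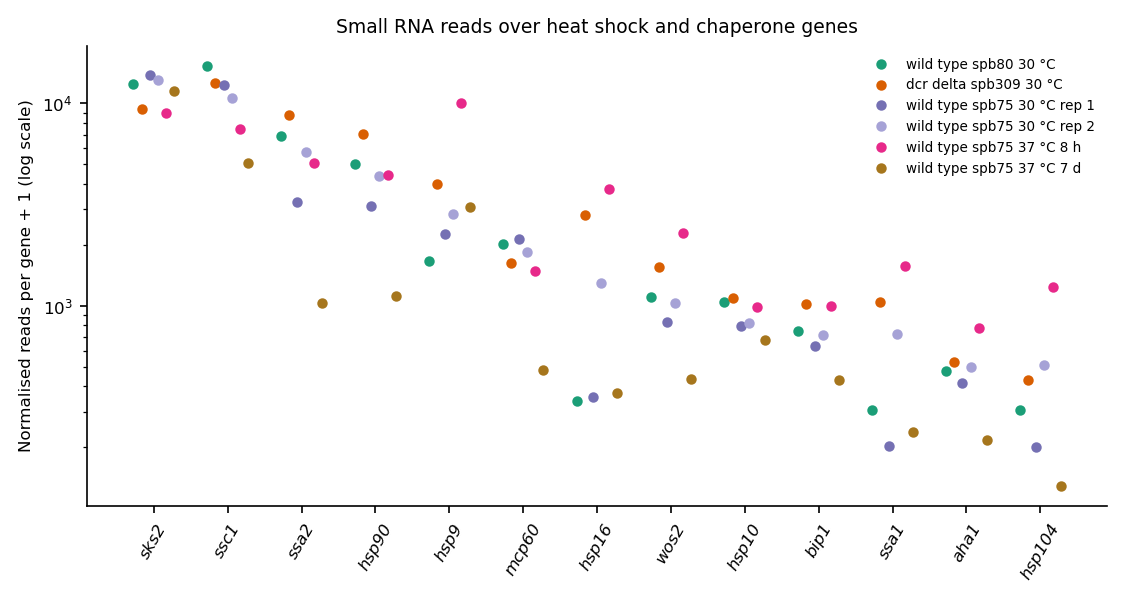
Points give normalised reads summed over the peaks of each gene plus 1, on a log axis, for the 13 heat shock and chaperone genes with the highest mean, 1 point per library. The hsp16 sum was 3771 at 8 hours and 2805 in dcr delta against 338 to 1300 in wild type at 30 °C, and the ssa2 sum was 1034 at 7 days against 3271 and 5752 in spb75 at 30 °C, with the median of all heat shock peaks at 8 hours turning from 0.42 to -0.69 under total-read scaling.

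All 159 tRNA peaks lay above 0 at 8 hours, with a median of 1.78, or 0.69 under total-read scaling, but limma called 0, also adjusted over the list alone, with 42 at an unadjusted p under 0.05. The highest was SPCTRNAHIS.04 (III, 1844633 to 1844712), at 56522 ± 2216 normalised reads (n = 2) and 347243 at 8 hours (2.62, SE 1.61). Of snRNA and snoRNA peaks (median 1.06, or -0.08 under total-read scaling) 2 rose, in snoR58 (2.31) and snoR47 (2.67), and adjusted over the list alone 17 rose and 1 fell. Pericentromeric repeats had a median of -0.49 with 0 called by limma, also adjusted over the list alone, and 1 at an unadjusted p under 0.05. That median was 0.13 without spb75 replicate 1, -1.01 without replicate 2 and -1.59 under total-read scaling. Subtelomeres had a median of -0.57, with 41 of 44 peaks below 0, -0.96 without replicate 2, and 0 called in either form, 5 of them at an unadjusted p under 0.05.

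The remaining lists gave medians of 0.89 for rRNA (-0.21 under total-read scaling, 0.10 without spb75 replicate 2), 0.67 for meiotic genes (-0.40 under total-read scaling, 0.39 without replicate 2), -0.27 for housekeeping (-0.46 without replicate 1, -0.02 without replicate 2), -0.42 for ribosomal protein genes, -0.65 for the mating-type region (-0.19 without replicate 2) and 0.22 for other non-coding RNA (-0.88 under total-read scaling, -0.03 without replicate 2). Against replicate 2 alone the rRNA median was 1.83. Of other non-coding RNA 4 rose and 2 fell, in both forms. Adjusted over the list alone 1 meiotic peak rose, in ste11, the gene of the meiotic regulator (2.04), and 0 of 6 genes with reads summed per gene, none of them at an unadjusted p under 0.05 in limma. The 1 Tf2 or LTR peak tested (3.24) overlaps the tRNA gene SPATRNAVAL.01 and was not called over all peaks or among tRNA peaks, and adjusting over a list of 1 leaves its unadjusted p under 0.05 as it is. None of the rRNA, housekeeping, ribosomal protein or mating-type peaks passed limma, with 1, 0, 19 and 2 at an unadjusted p under 0.05.

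How cells look after prolonged heat was asked with the 7 day library against spb75 at 30 °C. Reads on pericentromeric repeats made up 5.41% (95% Wilson interval 5.39 to 5.42%) against 19.3% ± 4.49 (SD, n = 2), those on subtelomeres 0.0384% (0.0370 to 0.0398%) against 0.210% ± 0.0178, and tRNA fragments 58.6% (58.6 to 58.6%) against 35.5% ± 5.07. Heat shock genes lay below 30 °C as a group, with a median of -0.85. Single peaks that passed the test numbered 4, in SPNCRNA.1606, mug14, SPBPB21E7.08 and nam3.

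By limma 2 of 8274 peaks rose and 2 fell, with 780 at an unadjusted p under 0.05. SPNCRNA.1606 (II, 3493620 to 3493656) rose by 3.94 (SE 0.62, adjusted p = 0.0415) from 13 and 5 reads to 70, and mug14, the gene of an adducin-like protein (II, 128860 to 128895, coding sequence), by 3.33 (SE 0.55, adjusted p = 0.0415) from 15 and 8 reads to 61. The pseudogene SPBPB21E7.08 (II, 73189 to 73221) went from 54 and 28 reads to 1, 20.9-fold lower with an interval of 3.65 to 836 (adjusted p = 0.0415). The lncRNA nam3 (II, 4465559 to 4465597) went from 79 and 31 reads to 2, 14-fold lower (3.79 to 117, adjusted p = 0.0490). All 4 calls were lost with median-of-ratios factors, with total-read scaling, under which 2 other peaks fell, without the filter and with all 3 wild-type libraries as control. Total-read scaling put the median of all peaks at -0.50.

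Among peaks that missed the threshold, wis2, a cyclophilin gene (I, 4930187 to 4930239), held 34 and 33 reads at 30 °C and 0 at 7 days, at least 5.69-fold lower (adjusted p = 0.0913). IRC1-L and SPNCRNA.3688 had a log2 ratio of -3.38 (SE 0.70, adjusted p = 0.0913) and SPNCRNA.3675, another centromeric lncRNA, -3.19. SPATRNAILE.02 stood at 3.41 (adjusted p = 0.128), SPATRNAALA.06 at 3.14, SPNCRNA.3054 at 3.10 and the snoRNA sno20 at 3.0. SPNCRNA.3016 stood at 3.17, SPBC24C6.03 at 2.85 and the peak on no feature on chromosome II (1947899 to 1947951) at 3.18, while ppk31, a kinase gene, held 5 reads against 0 and 1 at 30 °C (19.6-fold, 2.19 to 927). A subtelomeric peak on no feature (I, 7004 to 7131) held 1238 and 21 reads in the 30 °C replicates and 3 at 7 days (107-fold lower, 36.5 to 520), a ratio that rests on replicate 1. The transporter gene mfs3 and rpt6 held 1 read each at 7 days (13-fold lower, 2.23 to 524, and 12.2-fold lower, 2.09 to 493), and SPNCRNA.3327 next to cbm1 held 0, as did spb75 replicate 2 at 30 °C, so that its fall rests on the 119 reads of replicate 1 alone.

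Pericentromeric repeats at 7 days had a median of -2.00, with 40 of 41 peaks below 0, below all random sets. Over all peaks limma called 0 of them, with 26 at an unadjusted p under 0.05, while adjusted over the list alone 24 fell. The median was -1.45 without spb75 replicate 1 and -2.27 without replicate 2. Subtelomeres had a median of -1.80 with 0 called and 33 at an unadjusted p under 0.05, and adjusted over the list alone 31 fell. Their highest peaks, in SPNCRNA.4508 and tlh1, stood at -1.62 and -1.67.

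Of the 87 heat shock and chaperone peaks 73 lay below 0 at 7 days. The median of -0.85 was -0.46 without spb75 replicate 2 and -1.12 without replicate 1. None passed limma over all peaks, with 24 at an unadjusted p under 0.05, and adjusted over the list alone 16 fell. Of these 6 were in ssa2, an Hsp70 gene (-2.42 to -1.78), 3 in mcp60, the gene of a mitochondrial chaperonin, 3 in hsp90, 2 in hsp104 (-2.72 and -2.23), 1 in psi1 and 1 in aha1, both co-chaperone genes. With reads summed per gene, 3 of the 20 genes under these peaks, neighbours included, fell when adjusted over the list alone. The hsp104 sum was 128 normalised reads at 7 days against 356 ± 220 (n = 2), and that of ssa2 1034 against 4511 ± 1754. Meiotic genes had a median of 0.79 (1.23 without replicate 1) with 12 of 13 peaks above 0, and adjusted over the list alone 5 rose, 4 in ste11 (1.51 to 2.33) and 1 in mug8 (1.81). For meiotic genes 0 passed over all peaks, with 5 at an unadjusted p under 0.05.

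Medians at 7 days were 1.19 for tRNA, 1.13 for rRNA (0.29 without spb75 replicate 2), 0.93 for snRNA and snoRNA, -0.23 for stress genes (-0.43 without replicate 1, -0.04 without replicate 2), 0.17 for RNAi and heterochromatin genes (-0.24 under total-read scaling, -0.01 without replicate 2), 0.01 for ribosomal protein genes (-0.48 under total-read scaling, -0.10 without replicate 1), -0.60 for the mating-type region (-0.15 without replicate 2), 0.19 for other non-coding RNA (-0.33 under total-read scaling, -0.09 without replicate 2) and -0.04 for Tf2 or LTR. Against replicate 2 alone the rRNA median was 2.09. The housekeeping median was -0.0026 (-0.29 without replicate 1, 0.30 without replicate 2). With p adjusted over the list alone 10 snRNA and snoRNA peaks rose, with snu1 at 2.57 and sno20 at 3.0 and 2.75, 6 mating-type peaks fell, all in rpt6, and 3 other non-coding peaks rose and 8 fell, against 1 and 1 over all peaks. No tRNA, rRNA, stress, RNAi, housekeeping, ribosomal protein or Tf2 peak passed limma in either form, with 18, 0, 7, 2, 1, 4 and 0 at an unadjusted p under 0.05.

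The course of the heat response was followed by setting 7 days against 8 hours at 37 °C, as values of 1 library each without a test. Heat shock genes stood lower at 7 days, with a median log2 ratio of -1.68 and 76 of 88 peaks below 0, and stress genes at -1.02 with 56 of 65 below. Total-read scaling moved the median of all peaks to 0.58 and left these at -1.07 and -0.41. Pericentromeric repeats stood at -1.32, subtelomeres at -1.23, meiotic genes at 0.76, ribosomal protein genes at 0.43 and tRNA at -0.42, the last turning to 0.19 under total-read scaling. Beyond 2-fold lay 26.3% of 8274 peaks, 791 higher and 1382 lower at 7 days. In hsp104 (II, 3615009 to 3615101) 402 reads at 8 hours stood against 15 at 7 days (-4.40). In fes1 218.5 reads stood against 2, 90.6-fold lower with an interval of 24.8 to 753, in sec18, a vesicle fusion gene, 40 against 1 (33.2-fold, 5.63 to 1345), in wis2 32 against 0, at least 8.86-fold lower, and in cbm1 (I, 2936111 to 2936143) 17 against 0, at least 4.71-fold lower, although replicate 2 at 30 °C also held 0 there. Higher at 7 days were vht1 with 34 reads against 1 (40.9-fold, 6.87 to 1663), SPAC1B3.15C with 55 against 3 (22.1-fold, 7.17 to 110), SPBC409.08 with 18 against 1 (21.7-fold, 3.42 to 903), SPBC1271.10C with 76 against 6 (3.81), SPNCRNA.5053 (3.65), SPNCRNA.2089 (3.25), meu10 (3.13), fil1 (3.08), SPAPB1A11.03 (12.0-fold, 2.92 to 106) and SPAC2H10.01 (10.4-fold, 3.2 to 53.8). The other lower peaks of the 10 largest held 1 to 3 reads at 7 days, at the subtelomeric peak on no feature (I, 7004 to 7131, 35.4-fold, 11.9 to 174), prl65 (22.4-fold, 3.70 to 918), SPAC22H10.02 (26.6-fold, 4.44 to 1083), SPAC11D3.14C (24.9-fold, 4.14 to 1017) and SPNCRNA.862 next to cbm1 (26.6-fold, 4.44 to 1083), where replicate 2 at 30 °C was also almost without reads.

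How far wild-type strains differ was read from spb80 against spb75 at 30 °C, again as values. Beyond 2-fold lay 14.3% of 8274 peaks, 484 higher and 700 lower in spb80. That share was 22.7% without spb75 replicate 2. The median absolute log2 difference of spb80 was 0.540 from spb75 replicate 1 and 0.437 from replicate 2. Between the spb75 replicates it was 0.484, so strain differences cannot be told from differences between libraries. The 2 wide peaks next to the repeats of centromere III, at SPCTRNALYS.10 (1069488 to 1071259) and SPCTRNALYS.11 (1139504 to 1142285), stood at 3.02 and 3.29, and took 5.08% of reads in spb80 against 1.86% and 0.248% in the spb75 replicates. The dcr delta library, at 0.245%, was level with spb75 replicate 2, and its median of -2.52, with 0 peaks passing limma or at an unadjusted p under 0.05, rests on spb80 and replicate 1. At cbm1 (I, 2936055 to 2936086, 4.52) and SPNCRNA.862 (3.11) the ratio rests on the near absence of reads in spb75 replicate 2, and SPNCRNA.862 (I, 2939354 to 2939485) held 94.4 normalised reads in spb80 against 122 in replicate 1. Higher in spb80 were thi2, a thiamine synthesis gene (3.64), mal1, a maltase gene (3.35), SPAC32A11.02C (3.51), SPNCRNA.625 (2.93), fhn1 (2.74) and a peak on no feature (2.96). Lower were ade6, an adenine synthesis gene (III, 1317869 to 1317910), with 0 reads against 60 and 30.5, at least 13.8-fold lower, gld1 (-4.04, 25 reads against 640 and 319.5), the invertase gene inv1 (-4.02), lsd90 (-3.79), cnx1 (-3.44), rpl901 (-3.25) gpx1 (-3.17), and with 2 or 3 reads in spb80 SPCC737.04 (20.4-fold, 5.49 to 171), SPCC1739.08C (10.7-fold, 3.53 to 53.3) and eap1 (11.4-fold, 2.98 to 96.3). List medians were 0.69 for snRNA and snoRNA, 0.37 for rRNA, -0.28 for stress genes, 0.18 for pericentromeric repeats (-0.12 under total-read scaling, which put the median of all peaks at -0.30), 0.22 for ribosomal protein genes (-0.08) and 0.08 for tRNA (-0.23).

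**Figure D5:**
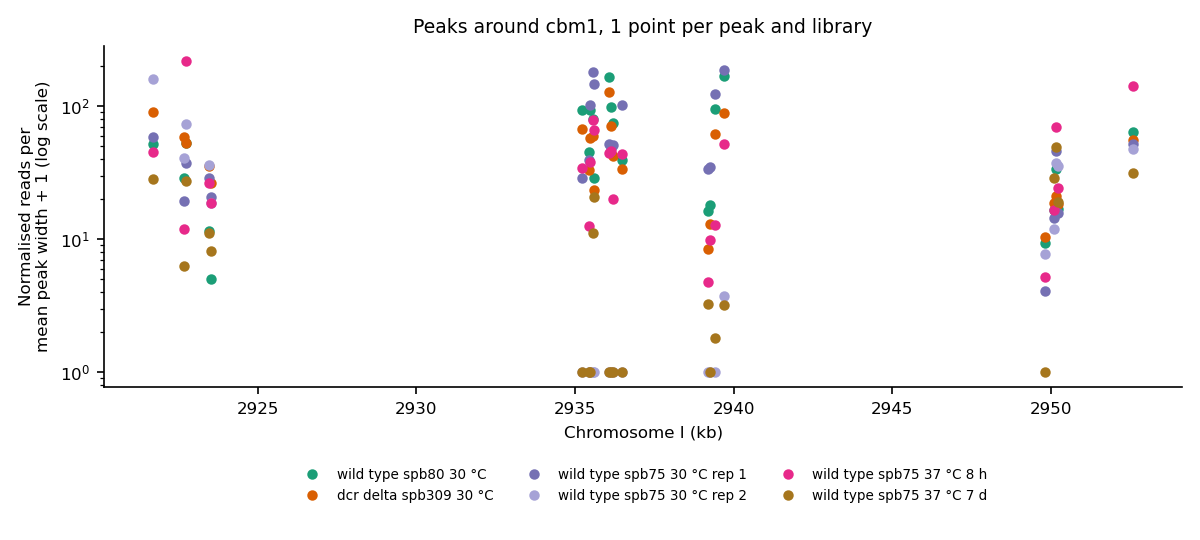
Points give normalised reads per mean peak width plus 1, on a log axis, of peaks around cbm1 in each library, against position in kb on chromosome I. Over the 13 peaks between 2935201 and 2939735 spb75 replicate 2 held 2.14 reads and the 7 day library 12.6, against 911 in spb80 and 1390 in spb75 replicate 1.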

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

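Of the tests below, those of dilution by tRNA fragments and of the chromosome stretch at cbm1 were chosen only after the result was seen, and the others before.

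The medians of heat shock and chaperone genes against each spb75 library at 30 °C lay on opposite sides of 0 at the time points of 37 °C. At 8 hours the median log2 ratio was 0.77 against replicate 1 and 0.32 against replicate 2, and at 7 days -0.46 and -1.12, a gap of 1.33 between the time points, and the difference was not tested. Medians of stress genes were 0.86 and 0.43 at 8 hours and -0.04 and -0.42 at 7 days, a gap of 0.873, and the difference was not tested. The opposite sides depend on the scaling. With total reads the heat shock medians were -0.69 at 8 hours and -1.33 at 7 days and the stress medians -0.53 and -0.71.

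The first pattern is the lower share of pericentromeric reads at 37 °C, 7.46% at 8 hours and 5.41% at 7 days. If a rise of tRNA fragments alone diluted the other reads, pericentromeric peaks would not fall relative to protein-coding peaks below the lowest wild-type library at 30 °C. At 8 hours their median relative to coding peaks was within 0.0067 of that library (a log2 of -0.0067, SD 0.633) and the ratio of summed reads, 1.13, was above its 0.759, so dilution could account for the lower share there and stays open. At 7 days the median lay lower by a log2 of -1.38, more than the SD of 0.633, which argues against dilution as the whole cause. The ratio of summed reads, 0.521, was lower only by a log2 of -0.543, within its SD of 0.623. Because the measures differ and 7 days has 1 library, dilution as the whole cause is not excluded. An effect of heat on heterochromatin siRNA and other technical causes stay open.

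The second pattern is the gap between the spb75 libraries at 30 °C, with r = 0.892. Their median squared difference was 56.9 times that of Poisson draws over 2139 peaks, but separate libraries exceed such draws in any case, so this decides nothing about counting noise, and the bound set for it was wrong. A preparation shared by replicate 1 with 8 hours and by replicate 2 with 7 days stays undecided, since rho was -0.0364 over 8188 peaks, many of them near the floor, and 0.142 over the 2288 peaks with a mean above 100, so the bound of 0 set for all peaks was wrong. For the 13 peaks around cbm1 the 7 day library held 3.29% of the predicted reads and replicate 2 0.373%, with 92.9% and 155% in the flanks. A stretch absent from both stays undecided, because 3 of the peaks held at least 10% of the predicted reads at 7 days, up to 42.3% (6 reads), and no biological explanation was tested.

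The third pattern is that peaks that rose at 8 hours also tend to lie above 0 in dcr delta against the 3 wild-type libraries. Of those also past the filter in the dcr delta comparison, 64.9% (50 of 77) still lay above the median of all peaks. The 95th percentile of matched random sets was 62.3%. That median was only -0.05, so subtracting it moved the values little, and scaling of the dcr delta library stays undecided. Shared control libraries could account for the pattern. Against spb80 alone, which is no control of the heat comparison, the share above 0 was 48.1% (37 of 77) and the random median 46.8%. A shared response of dcr delta and heat stays open, as 1 control library gives little power.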

How the results depend on the processing

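All tests here on scaling, filter, pseudocount and control libraries were chosen before the values were seen, except those with voom weights, with reads summed per gene and with the added 8 kept, which were chosen only after the result was seen. No paired analysis was run, because the labels give no pairs and the replicate numbers occur in 1 group only. In the sample order of the series, replicate 1 stands before 8 hours and replicate 2 before 7 days. Whether these were prepared together stays undecided, and the heat tests take them as unpaired. The DESeq2 test was not run, because the file holds signal and not counts, and a stricter peak threshold was not run, because the file holds no caller score. Without 1 of the 2 control libraries the heat comparisons have no residual degrees of freedom and give values with no test. The median was 19 to 47 reads per peak, and simulated 4-fold changes, up or down, were recovered at 32.8% by the dcr delta test. Under the 1 dispersion simulated, smaller changes on single peaks are mostly missed.

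Most falls in dcr delta were kept. Against 72 lower peaks the counts were 63 with the added 8 kept, 66 with pseudocount 10, 67 with voom weights and 92 with spb75 libraries as the only control, of which 63, 66, 67 and 67 were among the 72, and 71 to 92 with 1 control library left out. Of the 39 pericentromeric falls 38 or 39 were kept under every setting, and of the 31 subtelomeric falls 23 to 31. The calls of tho3 and snoR58 were each lost under some settings. The 2 higher peaks became 1 with median-of-ratios factors, 8 with total reads, 1 without the filter, 6 with pseudocount 10, 7 with voom weights, 7 with spb75 as the only control and 5 with reads summed per gene, and 2 to 7 with 1 control library left out. The pericentromeric median of -7.13 was -6.36 with pseudocount 10 and -6.36 with the added 8 kept, both of which raise low values by construction, and -7.43 to -6.87 with 1 control library left out.

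At 8 hours the 83 higher peaks became 42 with median-of-ratios factors, 0 with total reads, 260 with TMM factors without rRNA, tRNA, snRNA and snoRNA, 4 without the filter, 126 with pseudocount 10, 1 with all 6 libraries in 1 fit, 1 with all 3 wild-type libraries as control, 0 with both 37 °C libraries as 1 group and 2 with reads summed per gene. The 19 lower peaks became 8, 1, 71 and 1 under the first 4 of these, 1 in the fit of all 6 libraries, 3 with voom weights, 1 with 3 wild-type libraries, 0 with 1 group and 0 per gene. The fit of all 6 libraries also takes the 3 wild-type libraries as control, so these 2 fits are not separate checks. The pericentromeric median of -0.49 was -1.59 with total reads, -1.26 with both 37 °C libraries as 1 group and -1.01 to 0.13 with 1 control library left out. Pooling averages 8 hours with 7 days, and it put the heat shock median at -0.14, between 0.42 at 8 hours and -0.85 at 7 days. Why the counts of called peaks moved was not tested.

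At 7 days the 2 higher peaks became 43 with TMM factors without small RNA genes and 1 with pseudocount 10, and the 2 lower peaks 88 and 0. Higher peaks numbered 0 with total reads. Both counts were 0 with median-of-ratios factors, without the filter, in the fit of all 6 libraries, with voom weights, with 3 wild-type libraries as control, with both 37 °C libraries as 1 group and with reads summed per gene. The pericentromeric median of -2.00 was -1.26 with 1 group and -2.27 to -1.45 with 1 control library left out. The cause was not tested.

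The share of peaks beyond 2-fold between 7 days and 8 hours, 26.3%, was 36.5% with total reads. For spb80 against spb75, 14.3% became 18.3% with total reads and 16 to 22.7% with 1 library left out. Pearson's r of the spb75 replicates, 0.892, was 0.843 without small RNA peaks, 0.881 with pseudocount 0.1 and 0.912 with pseudocount 10. Their rho of 0.813 was 0.868 without the filter. For dcr delta with 8 hours r = 0.760 was 0.782 without the filter, 0.598 without small RNA peaks, 0.743 with pseudocount 0.1 and 0.807 with pseudocount 10, and rho = 0.604 was 0.709 and 0.571 for the first 2 of these. The cause was not tested. Of the other values 1043 stayed within the spread or on their side of the threshold, 126 moved, 32 were stronger and 141 weaker. Among them 52 list medians changed sign, none of them the pericentromeric or subtelomeric median in dcr delta.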

Other observations

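No tests were run on the values below, and the peaks were chosen only after the result was seen.

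The ade6 gene, often used as a marker in fission yeast strains, separates the strains. Its 5' peak (III, 1317308 to 1317340) held 17 reads in spb80 and 16 in dcr delta, against 2085 and 386 in the spb75 replicates, 1363 at 8 hours and 596 at 7 days. The labels do not give the ade6 allele of the strains. The subtelomeric peaks next to tlh1 (I, 7004 to 7665) held 378 reads in spb80, 0.833 in dcr delta, 1404.5 and 23 in the spb75 replicates, 140 at 8 hours and 3 at 7 days.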
